A study of Homo sapiens with 8 samples.

How the data were processed

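RNA was measured in 8 libraries of DLD1 cells, grown in RPMI1640 with 10% serum and plated 20 h before treatment, per the labels' protocols. Groups came from the labels as 4 groups of 2, and 0 columns of the table belonged to no sample. The authors deposited estimated counts per gene symbol for each library, not scaled by depth or length. Per the submitters' processing notes the tools were fastp, STAR and RSEM with the GRCh38 build, while their roles, versions and settings, the gene annotation and the strand setting were not given in the sources used here. Whether the values are RSEM's expected counts rounded by the authors was not stated. The deposited values were whole numbers, so rounding before the test changed nothing. Reads of near-identical copies (histones, heat shock and ribosomal protein genes) may have been split between them, and reads of overlapping or antisense genes cannot be told apart without the strand setting. In 28 rows the symbol had become a calendar date, 23 of which were tested and none named, and 2 such symbols each stood on more than 1 row.

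Counts were tested in R 4.3.3 with edgeR 4.0.16, by quasi-likelihood fits over all 8 libraries with a coefficient per group, TMM factors and filterByExpr (minimum count 10, minimum total 15), which kept 17199 of 58684 genes. Genes were called at a two-sided Benjamini-Hochberg adjusted p of 0.05. The fit had 4 residual and 13 prior degrees of freedom and a common biological coefficient of variation of 0.0602. Tests were 3 treatments against DMSO, OXA+Vola against each single agent, Vola against OXA, and the interaction, which is (OXA+Vola minus OXA) minus (Vola minus DMSO). CPM were taken from the library total scaled by its TMM factor, and log2 fold changes carry a prior count of 2 where log CPM was used. Total counts limit the precision, since 1 CPM stood for 21.8 to 41.5 counts, and the spread between libraries beyond counting error limits it further. Depth limits low genes most.

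The 30 gene lists, the markers of 4 other cell types, the rule for named genes and all alternatives except the GC and length fit were fixed before the data were examined. They covered p53 targets, G2/M and mitosis, G1/S and replication, histones, homologous recombination, nucleotide excision repair, DNA damage checkpoint, ribosomal proteins, ribosome biogenesis, the BCL2 family and caspases, NF-kB targets, interferon-stimulated genes, MHC class I, immediate-early genes, ATF4, the unfolded protein response, NRF2 targets, metallothioneins, cholesterol synthesis, heat shock, Wnt targets, enterocyte differentiation, hypoxia and glycolysis, mitochondrially encoded genes, CDK inhibitors, polo-like and Aurora kinases, platinum transport, lysosome and autophagy, mesenchymal genes and oxidative phosphorylation. Lists were tested by camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists of a comparison, with an estimated correlation and fry as alternatives.

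Named genes came from a rule. For each of 6 comparisons it took the 6 largest changes in each direction among called genes with a mean of at least 5 CPM in the higher group and non-overlapping replicates (not required for the interaction), up to 3 called members per list with the largest change, called members against a list's direction where 3 or fewer, and a panel of 17 genes. The genes printed are a subset of that pool, chosen after their values were seen, favouring calls that did not depend on a single library. CORO1A and PTPRC are named as cell type markers. Positions, GC content and length came from GENCODE 29, matched by symbol for 14654 tested genes (85.2%), 396 of them through an older symbol.

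Results were recomputed with other scaling factors, DESeq2 1.42.0, limma-voom, other filters, only the compared groups, a block on the replicate number, each library left out, and glmTreat against a 1.2-fold change. When a library was left out, its group's lone sample was assumed to vary like the other groups. A fit with each library's GC and length trend removed (splines with 3 and 1 interior knots, fitted on genes of at least 1 CPM) was added after seeing the data. The steps were tested on simulated data. For simulated OXA against DMSO, with 16820 genes, 50%, 64%, 88% and 100% of 50 genes changed by 1.3, 1.5, 2 and 4-fold were recovered, and 18 unchanged genes were called. With a simulated GC trend and no change between OXA+Vola and Vola, 6929 of 16869 genes were called, and 0 of 14481 with the trend removed. That simulated trend was linear, the same in both replicates, steeper than the one in the data and of opposite sign. These counts therefore do not estimate false calls in the data. They show that most simulated changes of 2-fold or more were recovered and that the simulated trend was removed. For simulated OXA against DMSO, with 200 genes changed in all, the 18 unchanged genes were a larger share of calls than the adjusted p threshold aims for. Why this share was larger was not tested.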

Results

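RNA from the human colorectal adenocarcinoma line DLD1 was measured by RNA sequencing after treatment with oxaliplatin (OXA), a platinum drug that binds DNA, with volasertib (Vola), an inhibitor of the mitotic kinase PLK1, or with both. The 8 libraries formed 4 groups of 2, namely vehicle (DMSO), OXA, Vola and OXA+Vola. Doses and durations were not given in the sources used here. Total counts were 41526969 and 28145013 in the DMSO libraries, 21752486 and 26898693 with OXA, 37966201 and 36627772 with Vola, and 35113111 and 25796263 with OXA+Vola, and 1 CPM (library-scaled counts) stood for 21.8 to 41.5 counts. Of 58684 genes in the table, 17199 passed the filter on low counts and were tested. Nothing stated that the replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Both libraries of each group differed by more than sampling noise, with a chi-square per degree of freedom between 4.85 for OXA+Vola and 8.02 for Vola.

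Markers of other cell types stayed low in these cultures of an epithelial line. Summed CPM per library ranged from 0.37 to 0.924 for 10 fibroblast genes, from 6.13 to 8.03 for 8 endothelial genes and from 0.0355 to 0.223 for 5 erythroid genes. The 13 leukocyte genes summed to between 53.1 and 69.3 CPM, of which CORO1A, an actin-binding protein gene, gave 49.5 to 65.3 CPM, while PTPRC reached at most 0.0527 CPM. The share of counts from mitochondrially encoded genes lay between 0.406% and 0.536%.

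Libraries also differed by the GC content of transcripts, and this trend moved with the groups. The mean slope of log2 CPM on GC, per 10 percentage points and over 10203 coding genes, was 0.03 for DMSO, -0.12 for OXA, -0.05 for Vola and 0.14 for OXA+Vola. Both Vola libraries differed by 0.09 and both OXA libraries by 0.07. A cubic fit on GC content alone, over 10489 genes of at least 5 mean CPM, accounted for part of the variance of log2 fold changes. Its share was 19.3% for OXA, 12% for Vola and 17.2% for OXA+Vola against DMSO. It was 45.4% for OXA+Vola against OXA, 55.5% for OXA+Vola against Vola, 55% for the interaction and 5.2% for Vola against OXA. Counts and list tests were therefore repeated with each library's GC and length trend removed, an alternative chosen after seeing the data. Where this ended a list call, the list median is given before and after, and why these calls ended was not tested. Such a loss does not mean that the members were no longer called.

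**Figure D1:**
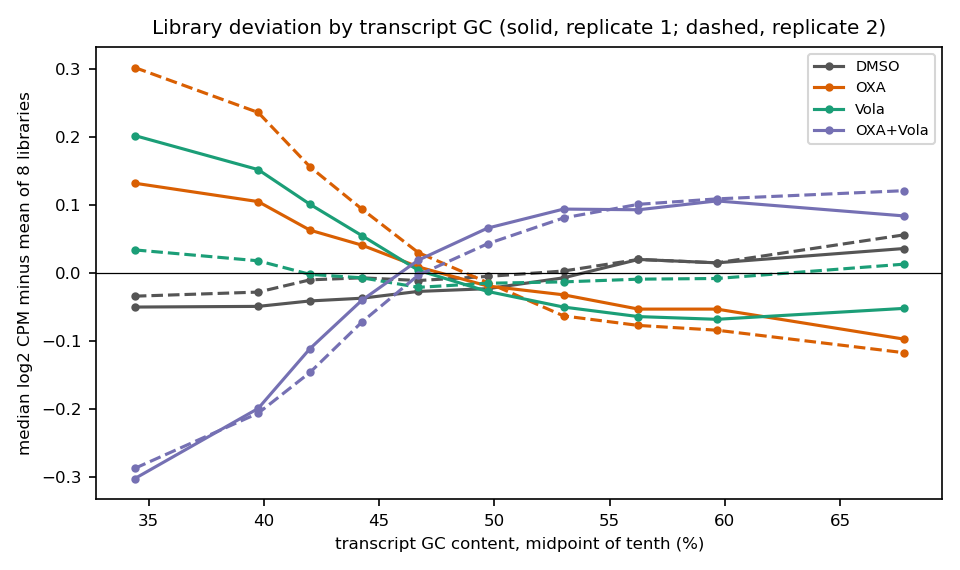
Median deviation of log2 CPM from the mean of the 8 libraries (vertical axis) in 10 bins of genes by transcript GC content (horizontal axis, percent), with a line per library, solid for replicate 1 and dashed for replicate 2. Mean slopes per 10 percentage points of GC were 0.14 for OXA+Vola and -0.12 for OXA.

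The first comparison asked what OXA alone changed. TXNIP, whose product binds and inhibits thioredoxin, rose from 40.6 ± 2.73 CPM in DMSO to 173.4 ± 10.5 CPM with OXA (SD, n = 2 each), and its paralog ARRDC4 rose by 1.39 on the log2 scale. CYR61 and CTGF, secreted matrix proteins and targets of YAP, rose by 1.75 and 1.37. The sharpest falls included CAPN15, a calpain family gene, from 128.9 ± 4.33 to 34.3 ± 2.66 CPM, PYCRL, a proline synthesis gene, by -1.74, and SLC19A1, the reduced folate carrier, by -1.56 on the log2 scale. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 6.2e-11 for TXNIP (log2 fold change 2.10, SE 0.08) and 6.8e-11 for CAPN15 (-1.91, SE 0.08). In GRCh38 with GENCODE 29 genes, TXNIP lies on chromosome 1 from 145992435 to 145996600 and CAPN15 on chromosome 16 from 527717 to 554636.

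Genes of cholesterol synthesis, the unfolded protein response and the ATF4 program were lower with OXA. Of 24 measured cholesterol synthesis and SREBP2 target genes, 20 fell and 0 rose, and 20 fell when adjusted over the list alone. INSIG1, a sterol-sensing regulator on chromosome 7 from 155297776 to 155310235, went from 63.4 ± 4.86 to 22.1 ± 1.59 CPM (SD, n = 2), and SQLE and MSMO1, enzymes of the pathway, each changed by -0.97 on the log2 scale. Of 22 unfolded protein response genes, 14 fell and 1 rose (16 and 2 adjusted over the list alone). Among them HSPA5, the main chaperone of the endoplasmic reticulum, changed by -1.14 and XBP1, a transcription factor of the response, by -0.95. Of 34 ATF4 and amino acid response genes, 22 fell and 2 rose (25 and 3 adjusted over the list alone), with DDIT4, an inhibitor of mTORC1, at -1.50 and CHAC1, a glutathione-degrading enzyme gene, at -1.27. The 2 that rose were PPP1R15A, a phosphatase subunit gene that restores translation, at 1.04 and GDF15, a secreted stress cytokine gene, at 0.53. Of 18 heat shock genes 10 fell and 0 rose (11 and 0 adjusted over the list alone), among them HSPA8 at -0.74, and HSPA1B at -1.30 shares reads with its near-identical copy HSPA1A. In limma's camera test with a preset correlation, adjusted p was 1.27e-10 for cholesterol synthesis, 8e-08 for the unfolded protein response, 9.53e-08 for ATF4 and 0.000129 for heat shock. None of these calls held when the correlation was estimated, with adjusted p = 0.266 with an estimated correlation for the first 3 and 0.637 for heat shock. By fry all were called lower, at adjusted p = 0.00421, 0.00159, 0.00159 and 0.0319 in that order.

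Immediate-early and inflammatory genes were higher with OXA. Of 30 immediate-early and AP-1 genes, 21 rose and 1 fell (24 and 2 adjusted over the list alone), including EGR1, an early transcription factor gene, at 1.07, and MYC was the member that fell, at -0.41. Of 27 NF-kB targets, 12 rose and 3 fell (14 and 3 adjusted over the list alone). BIRC3, an inhibitor of apoptosis, rose by 1.27 and ICAM1, an adhesion molecule gene, by 0.92, while CXCL5, a neutrophil chemokine gene, fell from 715 ± 12.4 to 356.4 ± 42.4 CPM (SD, n = 2). Camera gave adjusted p = 1.7e-08 and 0.00267 for these lists, and adjusted p = 0.266 with an estimated correlation for each. Of 20 mesenchymal genes, 7 rose and 0 fell (7 and 0 adjusted over the list alone), with TGFB2 at 0.96 (camera adjusted p = 0.0286, adjusted p = 0.458 with an estimated correlation). That call ended without DMSO replicate 2 (adjusted p = 0.0573), Vola replicate 1 (0.0637) or Vola replicate 2 (0.0642) and with a stricter filter (0.0918).

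Replication-dependent histone genes fell in 30 of 47 measured members and rose in 0 (32 and 1 adjusted over the list alone), with HIST1H2BM at -0.98. These are near-identical copies whose counts are uncertain. Camera gave adjusted p = 1.27e-10, and adjusted p = 0.266 with an estimated correlation. Among 34 homologous recombination and Fanconi anaemia genes 17 rose and 1 fell (19 and 1 adjusted over the list alone), with FANCM, a DNA translocase gene, at 0.61 (0.34 with the GC and length trend removed). Of 27 nucleotide excision repair and translesion genes 12 rose and 1 fell (12 and 2 adjusted over the list alone), including the translesion polymerase gene POLK at 1.00. Of 78 ribosomal protein genes 17 fell and 0 rose (17 and 0 adjusted over the list alone), with RPL3 at -0.60, in a family whose pseudogenes share reads. Of 19 Wnt target genes 5 fell and 1 rose (5 and 1 adjusted over the list alone), with EPHB2, a receptor of crypt cells, at -1.19. These 4 lists had camera adjusted p of 0.000502, 0.00312, 2.4e-06 and 0.00883, and adjusted p = 0.637, 0.439, 0.669 and 0.439 with an estimated correlation. All 4 calls also ended once the GC and length trend was removed, at adjusted p = 0.758, 0.251, 0.406 and 0.0826, while the medians went from 0.21 to 0.09, from 0.13 to 0.11, from -0.10 to -0.07 and from -0.11 to -0.17.

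Among 77 G2/M and mitosis genes 21 rose and 15 fell with OXA (26 and 20 adjusted over the list alone), and the list was not called as counted (camera adjusted p = 0.996) but was called lower with the GC and length trend removed (adjusted p = 0.0171). PLK1 was at 112.7 ± 1.03 CPM with OXA against 124.8 ± 4.91 in DMSO (log2 fold change -0.15, edgeR adjusted p = 0.14), and passed the threshold with upper-quartile factors (-0.20) and with a stricter filter (-0.19). CDKN1A, the cell cycle inhibitor p21, stood at 12.8 ± 0.124 against 11.2 ± 0.915 CPM (0.20, adjusted p = 0.18), and passed with the GC trend removed (0.28, adjusted p = 0.037). The log2 fold change of MDM2, which encodes the p53 ubiquitin ligase, was 0.07 and did not pass. Its sign turned without OXA replicate 2 (-0.08) and with the GC trend removed (-0.14).

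In total 4435 genes were called with OXA, 2571 higher and 1864 lower, and 247 of them changed at least 2-fold. The split was 2074 higher and 2487 lower with upper-quartile factors. Without DMSO replicate 2 the count was 2844 and without OXA replicate 2 it was 2856. Genes near chromosome ends, CAPN15 among them, stood lower with OXA. With the GC and length trend removed, the median log2 fold change was -0.04 over 191 genes at 0 to 0.5 Mb and -0.12 over 360 genes at 1 to 2 Mb from the outermost annotated gene of a chromosome and 0.01 over 8116 genes beyond 10 Mb, a check made after seeing the data.

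**Figure D2:**
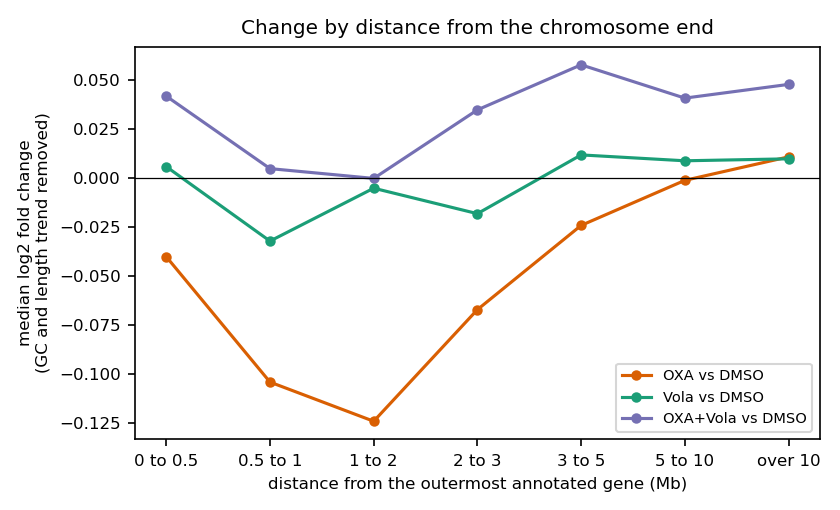
Median log2 fold change against DMSO with the GC and length trend removed (vertical axis) by distance from the outermost annotated gene of the chromosome (horizontal axis, Mb), with a line per treatment. At 1 to 2 Mb, its lowest point, the OXA median was -0.12 over 360 genes, against 0.00 for OXA+Vola and -0.01 for Vola.

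The second comparison asked what Vola alone changed. ARRDC3, an arrestin domain gene, rose by 2.02 on the log2 scale, and the AP-1 genes JUN, ATF3 and FOS rose by 1.92, 1.85 and 1.43. JUN went from 53.7 ± 3.47 to 203.1 ± 22.7 CPM and ATF3 from 9.55 ± 0.35 to 34.4 ± 1.41 CPM (SD, n = 2). The imprinted noncoding RNA H19 fell from 212 ± 21.8 to 79.75 ± 0.962 CPM, and CXCL5 and the immune receptor gene CRTAM changed by -0.93 and -1.20. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 1.3e-09 for JUN (SE 0.09) and 3.1e-08 for H19 (log2 fold change -1.41, SE 0.09). JUN lies on chromosome 1 from 58780788 to 58784327, ATF3 on chromosome 1 from 212565334 to 212620777 and H19 on chromosome 11 from 1995176 to 2001470.

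Cell cycle genes were lower with Vola. Of 77 G2/M and mitosis genes, 32 fell and 1 rose (43 and 1 adjusted over the list alone), with CDCA3, a mitotic entry factor, at -0.62 and CCNF, cyclin F, at -0.54. PLK1 itself, the kinase that volasertib inhibits, fell from 124.8 ± 4.91 to 92.0 ± 8.88 CPM (log2 fold change -0.44, edgeR adjusted p = 0.0008). Of 58 G1/S and replication genes, 24 fell and 1 rose (32 and 1 adjusted over the list alone), with the replicative helicase gene MCM3 at -0.42 and the polymerase gene POLD1 at -0.44. Of 47 histone genes, 41 fell and 0 rose (44 and 0 adjusted over the list alone), among them HIST1H2BE at -0.88, with the same doubt on near-identical copies. Camera gave adjusted p = 1.51e-13, 6.64e-12 and 1.26e-28, and adjusted p = 0.257, 0.257 and 0.185 with an estimated correlation. Of 61 ribosome biogenesis genes 16 fell and 1 rose (24 and 3 adjusted over the list alone), including BOP1, a pre-ribosomal RNA processing factor, at -0.46 (camera adjusted p = 1.63e-06, adjusted p = 0.477 with an estimated correlation). Of 24 cholesterol synthesis genes 8 fell and 0 rose (12 and 1 adjusted over the list alone), with FDFT1, squalene synthase, at -0.32 (camera adjusted p = 0.000303, adjusted p = 0.508 with an estimated correlation). By fry cholesterol synthesis (adjusted p = 0.112) and ribosome biogenesis (0.0684) missed the threshold.

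Early response genes, NF-kB targets and lysosomal genes were higher with Vola. Of 30 immediate-early and AP-1 genes 19 rose and 2 fell (20 and 2 adjusted over the list alone, camera adjusted p = 9.42e-12, adjusted p = 0.185 with an estimated correlation). Of 27 NF-kB targets 10 rose and 1 fell (10 and 1 adjusted over the list alone), with BIRC3 at 0.56. Of 36 lysosome and autophagy genes 6 rose and 0 fell (9 and 0 adjusted over the list alone), with the autophagosome gene MAP1LC3B at 0.70 and the autophagy receptor gene SQSTM1 at 0.54. Of 26 NRF2 targets 9 rose and 1 fell (10 and 2 adjusted over the list alone), with TXNRD1, thioredoxin reductase, at 0.41. Of 34 homologous recombination genes 6 fell and 0 rose (6 and 0 adjusted over the list alone), with FANCD2, a central Fanconi protein gene, at -0.49. Camera adjusted p was 0.00689, 0.00653, 0.029 and 0.00689 for these last 4 lists, and adjusted p = 0.257, 0.314, 0.477 and 0.623 with an estimated correlation. Without Vola replicate 2 all 4 calls ended, at adjusted p = 0.0702, 0.127, 0.31 and 0.217. Those of NF-kB targets and lysosomal genes also ended without DMSO replicate 1 (0.066 and 0.0574), and that of NRF2 targets without DMSO replicate 2 (0.123) or OXA+Vola replicate 2 (0.0559), with upper-quartile factors (0.0514) and with no filter (0.0547). Ribosomal protein and Wnt target genes had 3 of 78 and 3 of 19 members lower and 0 higher (2 and 4 lower adjusted over the list alone), at camera adjusted p = 0.00252 and 0.0192 and adjusted p = 0.646 and 0.477 with an estimated correlation. Both calls ended with the GC and length trend removed (0.708 and 0.16), though the medians were -0.04 before and after for ribosomal proteins and -0.10 and -0.09 for Wnt targets. The first also ended without Vola replicate 1 (0.199), and the second with no filter (0.0943) and without either DMSO library (0.101 and 0.0846), either OXA library (0.109 and 0.107) or Vola replicate 2 (0.15). By fry ribosomal protein (0.295), Wnt target (0.0684) and homologous recombination genes (0.224) missed the threshold. The DNA damage checkpoint was called lower with the trend removed (adjusted p = 0.00695, against 0.251 as counted).

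CDKN1A, on chromosome 6 from 36676460 to 36687339, rose to 20.9 ± 0.0919 CPM (log2 fold change 0.91, edgeR adjusted p = 2.8e-05), while 7 of 39 p53 target genes rose and 2 fell (7 and 2 adjusted over the list alone, camera adjusted p = 0.251). In total 2046 genes were called with Vola, 1182 higher and 864 lower, and 93 changed at least 2-fold. The split was 979 higher and 1207 lower with median-of-ratios factors, 1030 and 1229 with upper-quartile factors, 820 and 1172 with DESeq2, and 1198 and 1342 with a stricter filter. The count was 748 without DMSO replicate 1, 862 without DMSO replicate 2 and 761 without Vola replicate 1.

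**Figure D3:**
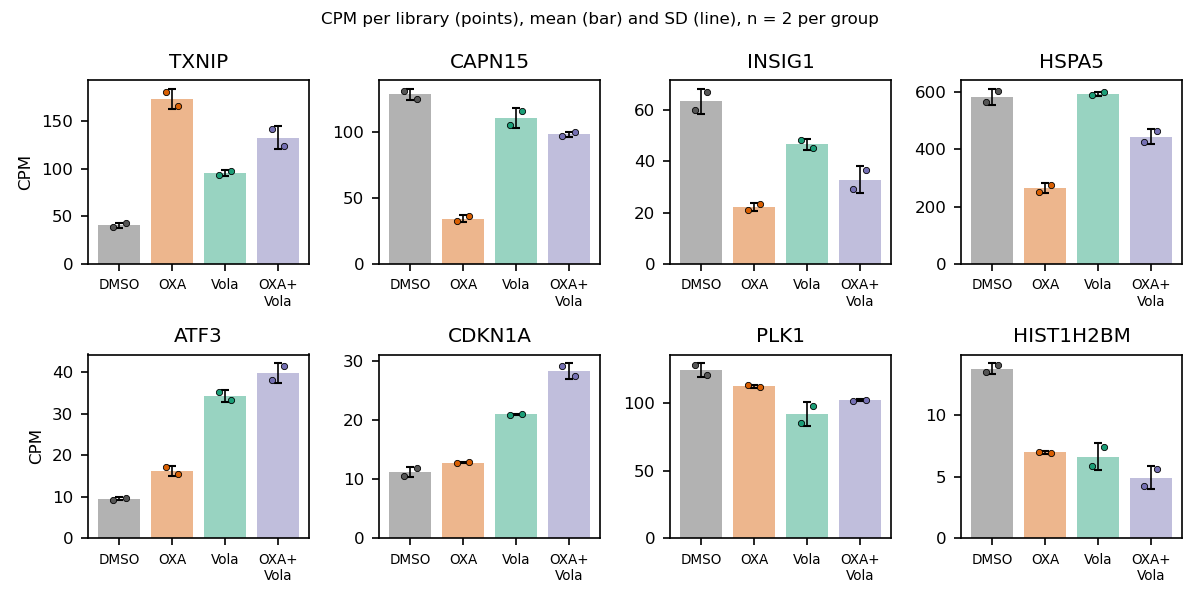
CPM (vertical axes) of 8 genes in each group, with a point per library, a bar at the mean and a line for the SD (n = 2). ATF3 stood at 34.4 CPM with Vola and 16.3 CPM with OXA, and HSPA5 at 264 CPM with OXA and 594.3 CPM with Vola.

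A direct test of Vola against OXA asked where the agents differed. Unfolded protein response genes were higher with Vola than with OXA in 18 of 22 members and lower in 0 (18 and 0 adjusted over the list alone), and ATF4 genes were higher in 21 of 34 and lower in 1 (22 and 1 adjusted over the list alone). Cholesterol synthesis genes were higher in 11 of 24 and lower in 0 (12 and 0 adjusted over the list alone). G2/M genes were lower with Vola in 45 of 77 and higher in 1 (46 and 1 adjusted over the list alone), and homologous recombination genes lower in 19 of 34 and higher in 0 (22 and 0 adjusted over the list alone). Camera adjusted p was 2.61e-10, 9.84e-07, 4.67e-06, 7.83e-10 and 7.77e-08, and adjusted p = 0.378, 0.378, 0.454, 0.378 and 0.434 with an estimated correlation. Heat shock genes were higher in 9 of 18 and lower in 0 (10 and 0 adjusted over the list alone), NRF2 targets higher in 12 of 26 and lower in 1 (15 and 2 adjusted over the list alone), and G1/S genes lower in 25 of 58 and higher in 7 (27 and 7 adjusted over the list alone), at camera adjusted p = 0.00098, 0.00291 and 0.000271 and adjusted p = 0.531, 0.378 and 0.455 with an estimated correlation. The NRF2 call ended without Vola replicate 2 (0.0588). Histone genes were lower in 16 of 47 and higher in 3 (17 and 3 adjusted over the list alone, camera adjusted p = 0.0066, adjusted p = 0.531 with an estimated correlation), a call that ended without OXA replicate 1 (0.0729) or Vola replicate 1 (0.0749) and by fry (0.0863).

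In the same comparison 6 more lists passed at camera adjusted p between 0.0066 (lysosome) and 0.0492 (platinum transport and ribosome biogenesis), with adjusted p between 0.378 and 0.632 with an estimated correlation, and none of the 6 passed with the GC and length trend removed. Their medians went from 0.22 to 0.26 for platinum transport, from 0.11 to 0.10 for lysosome, from 0.04 to 0.05 for ribosomal proteins, from -0.07 to -0.05 for ribosome biogenesis, from -0.16 to -0.06 for excision repair and from -0.16 to -0.11 for the DNA damage checkpoint. Of these, lysosome was not called without Vola replicate 2 (0.0622), the DNA damage checkpoint and ribosomal proteins without OXA replicate 2 (0.151 and 0.36) or Vola replicate 2 (0.0624 and 0.246), and ribosome biogenesis without DMSO replicate 1 (0.0602), OXA replicate 2 (0.106) or Vola replicate 1 (0.21). Platinum transport (4 of 18 higher and 2 lower, 9 and 4 adjusted over the list alone) was not called without any single library other than OXA replicate 1 and Vola replicate 1 (0.0595 to 0.175). Ribosome biogenesis and platinum transport were not called with upper-quartile factors (0.0671 for each), library size alone (0.0779 and 0.0686) or a stricter filter (0.113 and 0.0624), nor platinum transport with median-of-ratios factors (0.0547) or no filter (0.0586). The DNA damage checkpoint was not called with a stricter filter (0.0624), nor ribosomal proteins with no filter (0.0648), and fry called neither of these (0.0601 and 0.136) nor ribosome biogenesis (0.234). Fry did call platinum transport (adjusted p = 0.00267), lysosome (0.00729) and excision repair (0.0242). In total 3574 genes differed, 1686 higher and 1888 lower with Vola, a split of 2084 and 1546 with library size alone as the scale. The count was 2297 without OXA replicate 2 and 2361 without Vola replicate 2.

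Genes called for both agents against DMSO numbered 647 higher in both, 403 lower in both and 81 in opposite directions. Groups simulated with no gene changed, all from DMSO means and with simulated DMSO libraries shared by both contrasts, gave means of 0.15, 0 and 0 over 20 draws. With no gene changed hardly any calls were possible, so these means do not gauge the overlap. Independent lists would share 176.7, 93.6 and 257.3. Across 10743 genes, which are not independent replicates, log2 fold changes correlated at 0.494 against 0.49 simulated, with a covariance of 0.0325 against 0.00522, a difference of 0.0273. The 2 control libraries were not split, since each agent would then have 1, so part of any excess may come from them. Both agents also had GC slopes below that of DMSO (-0.12 for OXA and -0.05 for Vola, against 0.03). The simulated groups held no GC trend, and the overlap was not recomputed with the trend removed. Part of any excess may therefore come from that trend too. With a stricter filter 695 genes were lower in both.

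The third comparison asked what the combination changed against DMSO. CFTR, a chloride channel gene on chromosome 7 from 117465784 to 117715971, fell from 28.8 ± 0.33 to 6.89 ± 0.776 CPM (SD, n = 2). CXCL5, on chromosome 4 from 73995642 to 73998779, fell from 715 ± 12.4 to 224.8 ± 2.94 CPM, and CRTAM and H19 changed by -1.60 and -1.51 on the log2 scale. ATF3, JUN, TXNIP and FOS rose by 2.06, 1.96, 1.71 and 1.68, and CDKN1A rose to 28.3 ± 1.3 CPM from 11.2 ± 0.915 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 8.8e-08 for CFTR (log2 fold change -2.07, SE 0.14) and 6.6e-10 for ATF3 (SE 0.09).

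Mitotic genes were lower with OXA+Vola. Of 77 G2/M and mitosis genes 56 fell and 0 rose (58 and 0 adjusted over the list alone), with CENPE, a kinetochore motor gene, at -1.42, ASPM, a spindle pole gene, at -0.92 (-0.61 with the GC and length trend removed) and the proliferation marker MKI67 at -0.63. Of 58 G1/S genes 27 fell and 0 rose (28 and 1 adjusted over the list alone), with CDC7, a replication-initiating kinase gene, at -0.65. Of 47 histone genes 39 fell and 0 rose (43 and 0 adjusted over the list alone), with HIST1H2BM at -1.49. Of 61 ribosome biogenesis genes 24 fell and 0 rose (29 and 1 adjusted over the list alone), with UTP20 at -0.52. In camera adjusted p was 2.03e-17, 2.21e-07, 6.19e-19 and 1.39e-05, and adjusted p = 0.174, 0.295, 0.15 and 0.413 with an estimated correlation. Of 24 cholesterol synthesis genes 15 fell and 0 rose (16 and 0 adjusted over the list alone), with INSIG1 at -0.96 and HMGCS1 at -0.77. Of 18 heat shock genes 11 fell and 0 rose (11 and 1 adjusted over the list alone), with the chaperone gene HSP90AA1 at -0.56. Of 19 Wnt targets 7 fell and 0 rose (8 and 0 adjusted over the list alone), with the stem cell receptor gene LGR5 at -0.66. Of 34 ATF4 genes 12 fell and 5 rose (16 and 5 adjusted over the list alone), with PPP1R15A at 1.19. Camera adjusted p was 6.25e-06, 0.000271, 0.00245 and 0.0413 for these lists, and adjusted p = 0.379, 0.433, 0.295 and 0.427 with an estimated correlation. The Wnt call ended without OXA+Vola replicate 1 (0.0555). The ATF4 call ended without that library (0.0988), DMSO replicate 2 (0.0982), Vola replicate 1 (0.0526) or Vola replicate 2 (0.0524), with a stricter filter (0.0828) and by fry (0.052).

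Early response, NF-kB, lysosomal and NRF2 target genes were higher with OXA+Vola. Of 30 immediate-early genes 21 rose and 2 fell (24 and 2 adjusted over the list alone). Of 27 NF-kB targets 13 rose and 1 fell (15 and 2 adjusted over the list alone), with NFKB2 at 0.87. Of 36 lysosome and autophagy genes 18 rose and 0 fell (20 and 0 adjusted over the list alone), with SQSTM1 at 0.69 and the sialidase gene NEU1 at 0.67. Of 26 NRF2 targets 10 rose and 0 fell (12 and 1 adjusted over the list alone), with the ferritin gene FTL at 0.50. For these lists camera adjusted p was 3.56e-14, 9.57e-05, 2.69e-07 and 0.00245, and adjusted p = 0.148, 0.148, 0.148 and 0.295 with an estimated correlation.

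Calls for 4 more lists ended with the GC and length trend removed. Of 34 homologous recombination genes 17 fell and 0 rose (19 and 1 adjusted over the list alone), with BRCA1 at -0.62, and of 21 DNA damage checkpoint genes 9 fell and 0 rose (9 and 1 adjusted over the list alone), with the kinase gene ATR at -0.74. Of 22 unfolded protein response genes 7 fell and 3 rose (9 and 3 adjusted over the list alone), with HSPA5 at -0.40, and of 41 oxidative phosphorylation genes 9 rose and 1 fell (9 and 2 adjusted over the list alone), with COX8A at 0.34. As counted, camera adjusted p was 2.8e-05, 0.0155, 0.0155 and 0.0162, and adjusted p = 0.405, 0.405, 0.433 and 0.466 with an estimated correlation. With the trend removed it was 0.0846, 0.384, 0.0654 and 0.0846, while excision repair genes were then called higher (0.0187, against 0.659 as counted). The medians of these 4 lists went from -0.25 to -0.13, from -0.19 to -0.07, from -0.14 to -0.12 and from 0.05 to 0.13. The unfolded protein response call also ended without OXA+Vola replicate 1 (0.055), and that of oxidative phosphorylation without DMSO replicate 1 (0.197) or OXA+Vola replicate 1 (0.112).

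In total 3787 genes were called with OXA+Vola, 1712 higher and 2075 lower, and 221 changed at least 2-fold. With the GC and length trend removed the split was 2645 higher and 1525 lower of 4170. The median log2 fold change over the genes tested was then 0.046, against 0 as counted, so the fits are not centred alike. The count was 2116 without DMSO replicate 1, 2439 without DMSO replicate 2 and 2082 without OXA+Vola replicate 1.

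**Figure D4:**
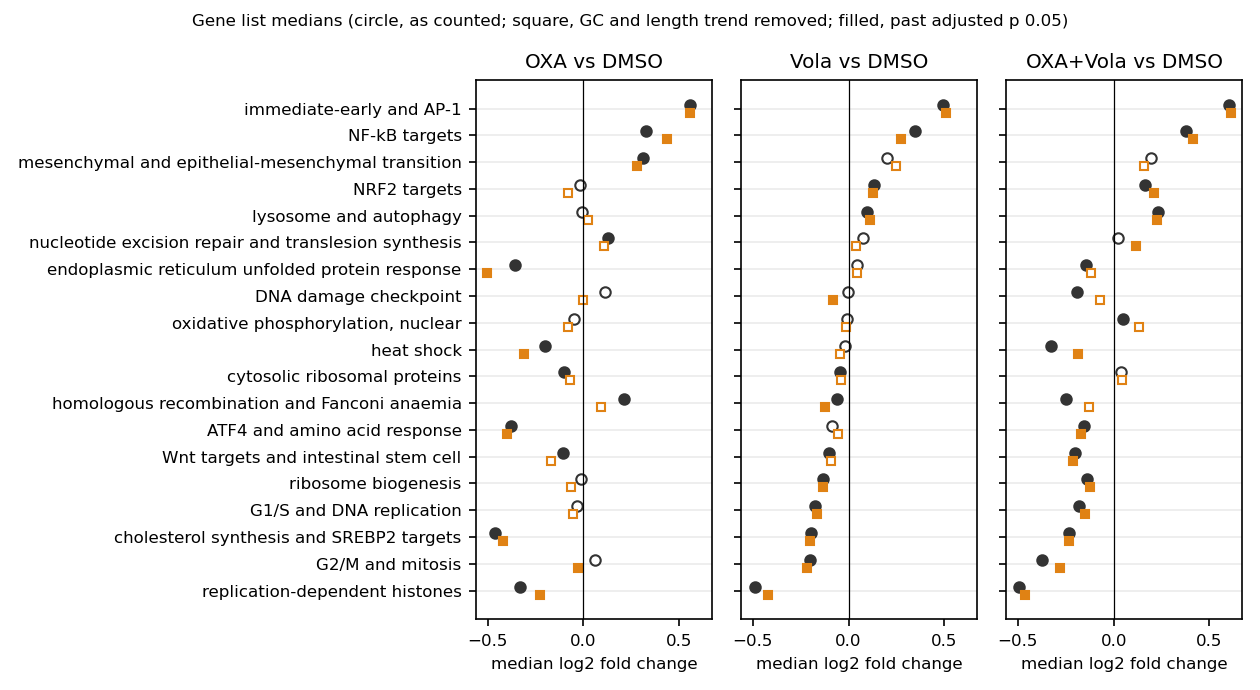
Median log2 fold change of the members of each gene list called as counted in at least 1 of the 3 comparisons with DMSO, as counted (circles) and with the GC and length trend removed (squares), filled where camera's adjusted p passed 0.05. The G2/M median was -0.20 with Vola and -0.37 with OXA+Vola.

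The fourth comparison asked what adding Vola to OXA changed. DDIT4 rose from 4.3 ± 1.1 CPM with OXA to 13.1 ± 2.53 CPM with both (SD, n = 2), and CAPN15 rose from 34.3 ± 2.66 to 98.5 ± 2.19 CPM. PIGQ, a gene of glycolipid anchor synthesis, rose by 1.47 on the log2 scale, CDKN1A by 1.14, and JUN and ATF3 by 1.29 each. CENPE, on chromosome 4 from 103105806 to 103198409, fell from 51.6 ± 14.3 to 16.3 ± 0.488 CPM, and MACC1, a gene tied to invasive growth, changed by -1.35. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 5.9e-09 for CAPN15 (log2 fold change 1.52, SE 0.08) and 6.6e-07 for CENPE (-1.67, SE 0.16). CENPE has a transcript GC of 35.3%, and with the GC and length trend removed the changes of CENPE and MACC1 were -1.07 and -0.75.

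Of 77 G2/M genes 41 fell and 5 rose (45 and 5 adjusted over the list alone), with CENPF at -1.23 (-0.78 with the GC and length trend removed). Of 47 histone genes 17 fell and 2 rose (17 and 2 adjusted over the list alone). Of 22 unfolded protein response genes 14 rose and 3 fell (14 and 3 adjusted over the list alone), with HERPUD1, a gene of protein degradation at the reticulum, at 1.07 and HSPA5 at 0.75. Of 26 NRF2 targets 13 rose and 1 fell (15 and 1 adjusted over the list alone), with FTL at 0.61. These 4 lists had camera adjusted p of 1.51e-09, 0.00552, 0.000413 and 0.000523, adjusted p = 0.433, 0.555, 0.433 and 0.433 with an estimated correlation, and 0.000133, 6.69e-11, 0.000281 and 0.0493 with the GC and length trend removed. The histone call ended without OXA+Vola replicate 2 (0.0765).

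The calls of 11 further lists ended with the trend removed. Homologous recombination genes fell in 23 of 34 members and rose in 1 (23 and 2 adjusted over the list alone), with BRCA2 at -1.05 (-0.45 with the trend removed), and went from adjusted p = 7.22e-07 to 0.186. Ribosomal protein genes rose in 41 of 78 and fell in 2 (46 and 2 adjusted over the list alone), with RPS9 at 0.42, and went from 2.16e-06 to 0.902. ATF4 genes rose in 19 of 34 and fell in 1 (20 and 1 adjusted over the list alone) and went from 0.000114 to 0.326, and lysosomal genes rose in 19 of 36 and fell in 1 (20 and 1 adjusted over the list alone), with SQSTM1 at 0.75, and went from 8.76e-06 to 0.231. For these 4 lists adjusted p = 0.433, 0.555, 0.433 and 0.433 with an estimated correlation, in the order homologous recombination, ribosomal proteins, ATF4 and lysosome. Their medians went from -0.53 to -0.24, from 0.16 to 0.12, from 0.20 to 0.20 and from 0.22 to 0.21. With the trend removed 21 homologous recombination members were called lower and 2 higher. Ribosomal proteins then had 40 higher and 2 lower, ATF4 16 and 0, and lysosome 19 and 0.

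Other lists that lost their call in this way were oxidative phosphorylation (18 of 41 higher and 2 lower, 18 and 2 adjusted over the list alone), hypoxia and glycolysis (15 of 34 and 4, 15 and 5 adjusted over the list alone), with NDRG1 at 1.12, and the DNA damage checkpoint (9 of 21 lower, 9 adjusted over the list alone), with the kinase gene ATM at -0.74 (-0.22 with the trend removed). Their camera adjusted p was 0.000413, 0.023 and 0.0146, adjusted p = 0.471, 0.433 and 0.471 with an estimated correlation, and 0.161, 0.667 and 0.874 with the trend removed, where the medians went from 0.15 to 0.14, from 0.17 to 0.09 and from -0.15 to -0.11. Members called higher and lower were then 21 and 0, 10 and 2, and 4 and 6. Cholesterol synthesis genes were higher in 11 of 24 and lower in 3 (12 and 3 adjusted over the list alone), immediate-early genes higher in 10 of 30 and lower in 2 (10 and 2 adjusted over the list alone), G1/S genes lower in 22 of 58 and higher in 7 (23 and 8 adjusted over the list alone) and excision repair genes lower in 13 of 27 and higher in 5 (14 and 5 adjusted over the list alone). At camera adjusted p = 0.0119, 0.012, 0.023 and 0.0319 and adjusted p = 0.558, 0.471, 0.558 and 0.501 with an estimated correlation, these 4 also depended on single libraries. Their medians with the trend removed were 0.20, 0.14, -0.03 and 0.03, against 0.16, 0.17, -0.07 and -0.22 as counted. Cholesterol synthesis was not called without OXA replicate 1 (0.0548) or OXA+Vola replicate 2 (0.06), immediate-early genes without OXA replicate 2 (0.0762), and G1/S and excision repair without OXA+Vola replicate 2 (0.0765 and 0.0894) or with a stricter filter (0.0639 and 0.0638). G1/S was also not called with upper-quartile factors (0.0885) or library size alone (0.056). Enterocyte (adjusted p = 0.0238) and mesenchymal genes (0.0493) were called lower with the trend removed and not as counted (0.557 and 0.361).

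In total 5704 genes differed, 2511 higher and 3193 lower, and 377 changed at least 2-fold. The split was 3577 higher and 2674 lower with upper-quartile factors and 2875 and 1691 with the GC and length trend removed. With that trend removed 2940 genes were called the same way as before and 161 in opposite directions. The median over the genes tested was then 0.054, against 0.009 as counted, so these fits are not centred alike.

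The fifth comparison asked what adding OXA to Vola changed. CENPE fell from 47.9 ± 9.91 to 16.3 ± 0.488 CPM (SD, n = 2), and CFTR and FAM111B, a protease gene, changed by -1.18 and -1.02 on the log2 scale (-0.62 for FAM111B with the GC and length trend removed). CYR61, on chromosome 1 from 85580761 to 85583962, rose from 65.8 ± 3.7 to 106.1 ± 8.14 CPM, ICAM1 by 0.61 and CDKN1A by 0.44. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 3.7e-05 for CENPE (log2 fold change -1.56, SE 0.15) and 4.9e-05 for CYR61 (0.69, SE 0.07). Of 18 heat shock genes 11 fell and 0 rose (11 and 0 adjusted over the list alone), with HSP90AA1 at -0.60, and of 22 unfolded protein response genes 9 fell and 0 rose (9 and 0 adjusted over the list alone), with HSP90B1 at -0.67. Camera gave adjusted p = 0.00467 and 0.00261, and adjusted p = 0.833 and 0.828 with an estimated correlation. Fry did not call heat shock genes (adjusted p = 0.117).

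Another 4 lists were higher and lost their call with the GC and length trend removed. Immediate-early genes rose in 6 of 30 (7 adjusted over the list alone), ribosomal protein genes rose in 11 of 78 and fell in 3 (11 and 3 adjusted over the list alone), lysosomal genes rose in 6 of 36 (10 adjusted over the list alone), and oxidative phosphorylation genes rose in 9 of 41 and fell in 2 (14 and 2 adjusted over the list alone). In order, camera adjusted p was 0.000722, 0.000722, 0.00261 and 0.00179, adjusted p = 0.828, 0.833, 0.828 and 0.833 with an estimated correlation, and 0.814, 0.511, 0.672 and 0.148 with the trend removed, where the medians went from 0.18 to 0.11, from 0.09 to 0.06, from 0.13 to 0.10 and from 0.11 to 0.12. Members called higher and lower with the trend removed were 6 and 1, 18 and 3, 7 and 1, and 16 and 0, in the same order. Fry called the lysosome list but not the others (0.0533, 0.18 and 0.0875 for immediate-early, ribosomal protein and oxidative phosphorylation genes). With the trend removed 6 lists not called as counted passed camera. Histone (adjusted p = 0.000113), Wnt target (0.000265), ATF4 (0.000287) and cholesterol synthesis genes (0.011) were lower, and homologous recombination (0.0155) and excision repair genes (0.011) were higher. For homologous recombination only 2 of 34 members were then called higher and 5 lower (median 0.063), against 4 and 14 as counted (median -0.068). For excision repair 7 of 27 were called higher and 1 lower (median 0.112), against 6 and 6 as counted (median -0.065). In total 3269 genes differed, 1046 higher and 2223 lower, and 90 changed at least 2-fold. The split was 2005 higher and 2018 lower with upper-quartile factors, and 1313 and 701 of 2014 with the trend removed, with 1117 genes called the same way in both. The median over the genes tested was 0.037 with the trend removed, against -0.001 as counted. The count was 1431 without Vola replicate 1 and 1669 without OXA+Vola replicate 1.

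The interaction asked where both agents together changed a gene by more or less than the sum of each alone on the log2 scale. CAPN15 (1.74), PYCRL (1.59) and ARFRP1 (1.51), a GTPase gene on chromosome 20 from 63698642 to 63708025, stood above that sum, all 3 within 2 Mb of a chromosome end, as did HSPA5 (0.72), SDF2L1 (1.01), DDIT4 (1.08), INSIG1 (1.00) and SQLE (0.60). CENPE (-1.81), CEP290, a cilium gene (-1.74), AKAP9, a Golgi and centrosome scaffold gene (-1.76), RASSF9 (-1.89) and ARRDC3 (-1.73) stood below it. So did CYR61 (-1.06), CTGF (-0.82), EGR1 (-0.84) and ATF3 (-0.56), which each agent had raised alone. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 8.8e-08 for CAPN15 (SE 0.10) and 1.1e-05 for CENPE (SE 0.21). CENPE, AKAP9, CEP290, RASSF9 and ARRDC3 stood at -1.05, -1.04, -0.99, -1.19 and -1.11 with the GC and length trend removed.

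Cholesterol synthesis genes lay above the sum in 15 of 24 members and below it in 1 (15 and 1 adjusted over the list alone), and unfolded protein response genes above it in 9 of 22 and below it in 4 (10 and 5 adjusted over the list alone). Immediate-early genes lay below it in 13 of 30 and above it in 1 (13 and 1 adjusted over the list alone). Camera adjusted p was 0.000124, 0.0169 and 0.00108, adjusted p = 0.555 with an estimated correlation for each, and 0.00286, 0.00286 and 9.63e-11 with the trend removed. The unfolded protein response call ended without OXA replicate 1 (0.0651). Histone genes lay above the sum in 22 of 47 (32 adjusted over the list alone) and homologous recombination genes below it in 21 of 34 and above it in 1 (21 and 4 adjusted over the list alone), at camera adjusted p = 2.2e-08 and 0.00108, adjusted p = 0.555 with an estimated correlation, and 0.75 and 0.166 with the trend removed, where the medians went from 0.33 to 0.20 and from -0.42 to -0.08. Ribosomal protein genes lay above the sum in 34 of 78 and below it in 1 (38 and 1 adjusted over the list alone), ATF4 genes above it in 15 of 34 and below it in 2 (16 and 2 adjusted over the list alone), and oxidative phosphorylation genes above it in 12 of 41 and below it in 2 (18 and 2 adjusted over the list alone). For these 3 camera gave 2.2e-08, 0.000294 and 0.00108, with adjusted p = 0.555 with an estimated correlation and 0.997, 0.428 and 0.166 with the trend removed, where the medians went from 0.20 to 0.16, from 0.30 to 0.26 and from 0.15 to 0.20. Members called above and below the sum were then 34 and 0, 13 and 2, and 18 and 0, against 16 and 0 for histones and 3 and 6 for homologous recombination. With the trend removed G1/S genes were called above the sum (adjusted p = 0.0279) and NF-kB targets (0.0135) and mesenchymal genes (0.00286) below it, and none of these 3 as counted. In total 4533 genes were called, 1755 above and 2778 below the sum. The split was 2913 and 2305 with upper-quartile factors, and 1797 and 1064 of 2861 with the trend removed, with 1706 genes called the same way in both and 89 in opposite directions. The median over the genes tested was 0.044 with the trend removed, against -0.001 as counted.

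**Figure D5:**
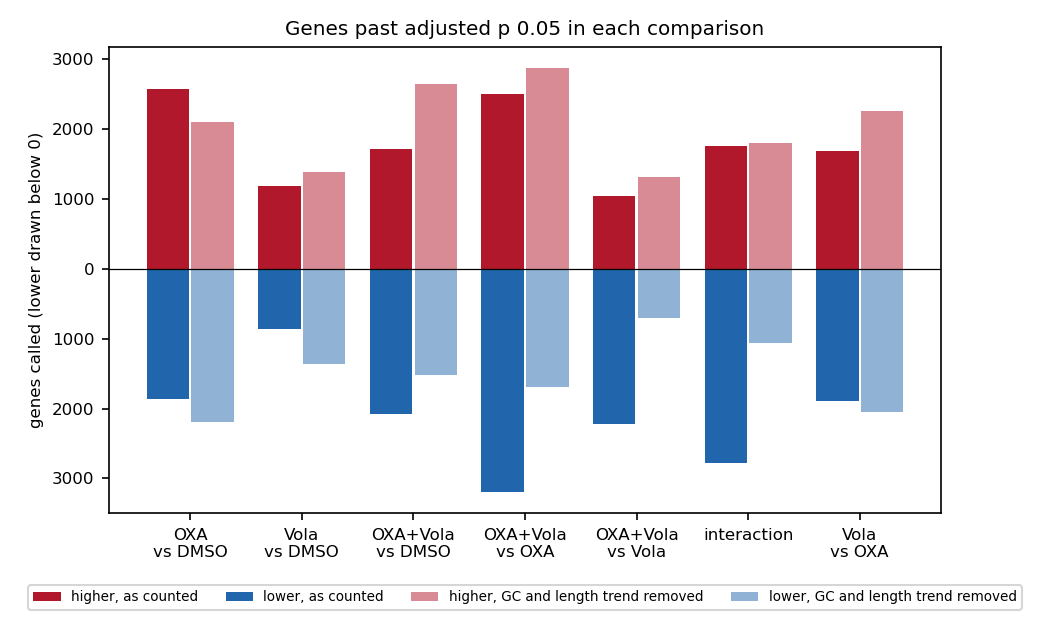
Number of genes past adjusted p 0.05 (vertical axis, lower genes drawn below 0) in each comparison (horizontal axis), as counted and with the GC and length trend removed. For OXA+Vola against Vola 1046 genes were higher and 2223 lower as counted, and 1313 and 701 with the trend removed. The median log2 fold change over the genes tested was -0.001 and 0.037, so the fits are not centred alike.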

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

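The tests of GC content in this part used a trend seen first in these data. The depth test and the share of variance between groups were chosen after the result was seen, as was the fit with the trend removed.

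The effect of Vola differed with and without OXA, by edgeR's quasi-likelihood test of the interaction, in 4533 genes. Gene lists for which camera found the same kind of difference had median interactions of 0.33 for histones, -0.422 for homologous recombination, -0.233 for nucleotide excision repair, 0.204 for ribosomal proteins, -0.31 for immediate-early genes, 0.295 for ATF4, 0.169 for the unfolded protein response, 0.382 for cholesterol synthesis, 0.163 for hypoxia and glycolysis, 0.168 for lysosome and autophagy and 0.153 for oxidative phosphorylation, on the log2 scale. None of these 11 calls held with an estimated correlation (adjusted p = 0.555 for each). By fry all 11 were called in the same direction (adjusted p from 0.025 to 0.0301). The hypoxia call ended without OXA replicate 2 (adjusted p = 0.0543), Vola replicate 2 (0.0597), OXA+Vola replicate 1 (0.0513) or OXA+Vola replicate 2 (0.0542), and the lysosome call without OXA replicate 1 (0.0651), Vola replicate 1 (0.0626) or OXA+Vola replicate 1 (0.0581). The excision repair call ended without DMSO replicate 1 (0.1), OXA replicate 1 (0.0651), Vola replicate 2 (0.0601) or OXA+Vola replicate 2 (0.146), and that of the unfolded protein response without OXA replicate 1 (0.0651). A stricter filter ended the calls of hypoxia (0.074), lysosome (0.0684) and excision repair (0.0841), the last of which also ended with median-of-ratios factors (0.0568) and upper-quartile factors (0.0842).

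Single genes with an interaction above the sum of the agents were CAPN15 (1.74), PYCRL (1.59), ARFRP1 (1.51), DDIT4 (1.08), SDF2L1 (1.01), INSIG1 (1), HSPA5 (0.72), HIST1H4I (0.69), XRCC3 (0.65), SQLE (0.60), RPS9 (0.52), RPL10A (0.49), LAMP1 (0.47) and PLK1 (0.30). Below the sum were RASSF9 (-1.89), CENPE (-1.81), AKAP9 (-1.76), CEP290 (-1.74), ARRDC3 (-1.73), POLK (-1.63), BRCA2 (-1.38), RAD50 (-1.13), CYR61 (-1.06), EGR1 (-0.84), CTGF (-0.82), SLC7A11 (-0.69), PPP1R15A (-0.62), ATF3 (-0.56) and SC5D (-0.55). With the GC and length trend removed, values that shrank by over 1.5 times were those of RASSF9 (-1.19), ARRDC3 (-1.11), CENPE (-1.05), AKAP9 (-1.04), CEP290 (-0.99), POLK (-0.93), RAD50 (-0.64), BRCA2 (-0.61) and RPS9 (0.32), and the calls of PLK1 (0.12), SC5D (-0.02) and SLC7A11 (0.07) ended. The PLK1 call also ended without DMSO replicate 1 (0.26), OXA replicate 1 (0.30), OXA replicate 2 (0.29), Vola replicate 1 (0.20) or OXA+Vola replicate 1 (0.31).

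GC content alone accounted for 55% of the variance of the interaction across 10489 genes. Among all ways to pair the 8 libraries, 2 gave slopes as far apart as the real groups, the real one included. That share of 0.019 by exact enumeration argues against random variation between libraries. The 6 pairs of libraries of different groups within 1.1 times in depth differed in slope by at least 0.121. In 3 pairs of one group that differed by more in depth the difference was at most 0.072, which argues against sequencing depth as the whole cause. The limit of 1.1 was set after the slopes were seen. At a depth ratio of 1.134 DMSO replicate 1 and Vola replicate 2 differed by 0.041. Both Vola libraries, at a ratio of 1.037, differed by 0.09. The slope of OXA+Vola minus Vola in 436 long noncoding genes was 0.78 of that in 10203 coding genes, so the trend was not confined to coding genes. A fragment GC bias acting on any transcript may be the cause. A treatment that changes transcripts by GC content could act on noncoding genes too, so this ratio cannot decide between them. Of the variance of the slopes 92% lay between groups, as it would both for libraries prepared group by group and for a treatment that changes transcripts by GC content, so these cannot be told apart without preparation batches in the labels. Of the 11 lists above, cholesterol synthesis, the unfolded protein response and immediate-early genes were still called with the trend removed, at adjusted p = 0.00286, 0.00286 and 9.63e-11 by camera's preset correlation, though none held with an estimated correlation (adjusted p = 0.555). The other 8 lost their call, and why was not tested. Their medians went from -0.422 to -0.077 for homologous recombination, from -0.233 to 0.004 for excision repair, from 0.168 to 0.064 for lysosome, from 0.33 to 0.195 for histones, from 0.204 to 0.155 for ribosomal proteins, from 0.295 to 0.264 for ATF4, from 0.163 to 0.158 for hypoxia and from 0.153 to 0.195 for oxidative phosphorylation.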

How the results depend on the processing

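The fit with the GC and length trend removed was chosen after seeing the data, and the other alternatives were planned. Other scaling factors, DESeq2, limma-voom, no filter, only the compared groups and a replicate block left the total of called genes in each comparison within 1.5 times where run, although upper-quartile factors moved the higher calls from 1046 to 2005 for OXA+Vola against Vola and from 1755 to 2913 for the interaction. Shared calls were recomputed with DESeq2 and a stricter filter alone. Depth limits calls of small changes in low genes. Rounding was not run as an alternative because the deposited values were whole numbers, and a fit on only the compared groups was not run for the interaction, which uses every group.

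Against a 1.2-fold change glmTreat called 1216 genes for OXA, 194 for Vola and 733 for OXA+Vola against DMSO, 2319 for OXA+Vola against OXA, 661 against Vola, 2224 for the interaction and 796 for Vola against OXA, since it asks for a larger change. With an estimated correlation 0 lists were called by camera in any of the 7 comparisons, against 6 to 16 with the preset value, and fry called 2 lists for OXA+Vola against Vola, where the cause was not tested. Since the estimated correlation left no list called, a call lost with it does not tell lists apart. Over the 7 comparisons fry kept 73 list calls and ended 14. With the GC and length trend removed 2014 genes were called for OXA+Vola against Vola and 2861 for the interaction, and lists called were 6 for OXA+Vola against OXA, 6 for the interaction and 9 for Vola against OXA. With a stricter filter 695 genes were lower with both agents, where the cause was not tested.

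Leaving out each library in turn, with fewer samples, gave 2844 to 4565 genes for OXA, 748 to 2330 for Vola, 2082 to 3951 for OXA+Vola, 3917 to 5755 for OXA+Vola against OXA, 1431 to 3398 for OXA+Vola against Vola, 3421 to 4469 for the interaction and 2297 to 3596 for Vola against OXA. Lists called for Vola ranged from 7 (without Vola replicate 2) to 12. The counts moved by over 1.5 times for OXA without DMSO replicate 2 (2844) or OXA replicate 2 (2856), for Vola without DMSO replicate 1 (748), DMSO replicate 2 (862) or Vola replicate 1 (761), for OXA+Vola without DMSO replicate 1 (2116), DMSO replicate 2 (2439) or OXA+Vola replicate 1 (2082), for OXA+Vola against Vola without Vola replicate 1 (1431) or OXA+Vola replicate 1 (1669), and for Vola against OXA without OXA replicate 2 (2297) or Vola replicate 2 (2361).

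With the replicate number as a replicate block, 4040, 1620 and 3393 genes were called for OXA, Vola and OXA+Vola against DMSO, 5355 and 2847 for OXA+Vola against OXA and Vola, 4174 for the interaction and 3155 for Vola against OXA. The block ended 3 list calls, those of NRF2 targets for Vola (adjusted p = 0.0674) and of ribosome biogenesis (0.0605) and platinum transport (0.066) for Vola against OXA, and no other. Residuals of libraries with the same number correlated between -0.0745 and 0.087, which does not show that the numbers pair samples and cannot exclude it.

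Signs turned as follows, and the cause was not tested. Without OXA replicate 2 MDM2 went to -0.083 for OXA and 0.033 for OXA+Vola against OXA, within ranges of -0.083 to 0.201 and -0.25 to 0.033 over the libraries left out. With the GC and length trend removed MDM2 went to -0.139 for OXA, 0.139 for OXA+Vola, 0.279 and 0.088 for OXA+Vola against OXA and Vola, and 0.227 for the interaction. RPL7 went to 0.163 and UQCRB to 0.129 against OXA, and to 0.102 and 0.051 against Vola, STARD4 to 0.064 against OXA, and SLC7A11 to 0.068 for the interaction. For OXA+Vola against OXA, camera's direction or the list median turned, with medians of 0.028 for excision repair, -0.114 for the DNA damage checkpoint, 0.118 for ribosomal proteins and 0.144 for immediate-early genes. Against Vola they were 0.062 for ribosomal proteins, 0.112 for immediate-early genes and 0.096 for lysosome, and for the interaction 0.195 for histones, -0.077 for homologous recombination, 0.004 for excision repair and 0.064 for lysosome.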

Other observations

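The test of the chromosome ends against matched genes and, for the cell cycle lists, the fit with the trend removed and the tests on bootstrap intervals were chosen only after the result was seen.

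Lists not called by camera in any comparison with DMSO included p53 targets, with 6 of 39 members higher and 5 lower for OXA (6 and 5 adjusted over the list alone) and 10 higher and 4 lower for OXA+Vola (12 and 4 adjusted over the list alone). For OXA, 10 of 35 interferon-stimulated genes were higher and 1 lower (10 and 2 adjusted over the list alone, camera adjusted p = 0.293), 5 of 33 genes of the BCL2 family and caspases were higher and 5 lower (5 and 5 adjusted over the list alone, 0.933), and 4 of 18 platinum transport genes were higher and 4 lower (4 and 5 adjusted over the list alone, 0.346). MHC class I genes were higher in 2 of 15 for OXA (1 adjusted over the list alone, 0.563), metallothioneins in 1 of 4 (1 adjusted over the list alone, 0.996), CDK inhibitors and D cyclins in 3 of 13 (3 adjusted over the list alone, 0.563), and polo-like and Aurora kinases in 3 of 10 with 1 lower (3 and 2 adjusted over the list alone, 0.933). Enterocyte genes were higher in 2 of 17 and lower in 1 (1 and 1 adjusted over the list alone, 0.861), hypoxia and glycolysis genes in 5 of 34 with 8 lower (7 and 10 adjusted over the list alone, 0.293), and 1 of 13 mitochondrially encoded genes was lower (1 adjusted over the list alone, 0.933). Fry called platinum transport lower for OXA (adjusted p = 0.0461) and higher for Vola (0.00762) and OXA+Vola (0.0157). It also called interferon-stimulated genes higher for OXA (0.0461). For OXA+Vola fry called p53 targets (0.0434) and hypoxia and glycolysis (0.0139) higher, and polo-like and Aurora kinases lower (0.0223).

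Genes within 2 Mb of a chromosome end were lower with OXA. As counted, their median log2 fold change was -0.157 over 765 genes, and 0 of 10000 lists matched on GC content, length and expression (median -0.038) lay as low, a percentile of 0, which argues against those properties as the whole cause. With the GC and length trend removed the medians were smaller, at -0.04 for 0 to 0.5 Mb, -0.104 for 0.5 to 1 Mb and -0.124 for 1 to 2 Mb. Of 38 chromosome ends, 29 lay below the median of all genes with that trend removed, a share of 0.763, which argues against loss at a few ends. Below, too, matched lists are as counted and ends have the trend removed. OXA+Vola also lay low, with 1 of 10000 lists as low (0.017 against 0.053) and 27 of 38 ends below, while the Vola median lay within the central 95% of its matched lists (-0.046, from -0.047 to -0.019) with 23 of 38 ends below, and the differences between treatments were not tested. A response to the drug may be involved as a hypothesis, but neighbouring genes may vary together, which would make matched lists of single genes too narrow, and this stays open.

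G2/M, G1/S and histone lists were lower with Vola. With the GC and length trend removed the G2/M median was -0.216 (95% bootstrap interval -0.271 to -0.182), which argues against that trend as the whole cause. As counted 64 of 77 G2/M members lay below 0. The upper end of the interval of their median was -0.129, and these values were seen before the test. They show that G2/M transcripts were not raised as a set. Because they restate the fall, they cannot decide whether more cells were held in mitosis. A smaller share of cycling cells stays open as a hypothesis that these data did not test, since the highest upper end over all 3 lists (-0.118) only restates the falls. Members of a list may vary together, which would make bootstrap intervals over genes too narrow. No camera test of these lists held with an estimated correlation (adjusted p = 0.257, 0.257 and 0.185). By fry all 3 were called lower (adjusted p = 0.0203, 0.00762 and 0.00356).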
